A study of Mus musculus with 16 samples.

How the data were processed

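Ribosomal RNA-depleted total RNA of whole mouse retina was sequenced, per the labels, as single reads of 50 nt on an Illumina HiSeq after library preparation with a SMARTer kit. The submitters' processing notes name STAR, HTSeq, DESeq2 and the mouse build mm10, without versions, settings, annotation or the strand mode of counting. The authors deposited 3 tables, each of 1 injured group (GFP, HDAC5AA or HDAC5DAD) beside the same 4 uninjured libraries. The values per library are a normalized count signal: in the deposited tables every value was a whole multiple of 1 factor per library, so that reads could be recovered by dividing by it. All recovered values (100 of 100 percent in every library) lay within 0.01 of a whole read. The uninjured libraries had other factors in each table, and their recovered reads were equal between tables for all 78300 values compared in the HDAC5AA table and all 77980 in the HDAC5DAD table. The tables also hold, per the file headers, a log2 fold change, a p-value and an adjusted p-value by the authors. Their log2 fold change was smaller than the log2 ratio of the means for genes with large changes, as for Ecel1 (5.28 in GFP), as a shrunken estimate is. The deposited lists of higher and lower genes were exactly the genes with the authors' adjusted p under 0.1 (1194 and 1401 in GFP, 1214 and 779 in HDAC5AA, 1759 and 1345 in HDAC5DAD).

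The labels name 16 samples, and 15 were analysed: GFP replicate 1 was not analysed here, since the tables used hold no column for it. The tables hold 19961, 19714 and 19956 genes for GFP, HDAC5AA and HDAC5DAD, of which 19495 stand in all 3. The smallest read total of a gene was 36 in the GFP table, so genes with fewer reads had been left out before deposit. Recovered reads per library were 17427901, 23482507, 30970658 and 18748032 (Uninjured), 23274513, 17401942 and 17769198 (GFP replicates 2 to 4), 20727756, 24231065, 15722329 and 10939457 (HDAC5AA), and 13878984, 25930791, 21613142 and 18542734 (HDAC5DAD). To either side of a log2 fold change, the 95% interval reached a median of 0.23 in GFP and 0.22 in HDAC5AA against Uninjured. Gene IDs were matched to GENCODE mouse release 21 (mm10), which held 20190 of 20278, for coordinates, gene types and 49 symbols missing or turned into dates in the tables.

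The plan, the gene lists and the naming rule were fixed before the data were examined. It provided for edgeR if the tables held whole counts and for limma on log2 values if they held normalized values; the deposited unit is normalized, so limma was the main test and edgeR on the recovered reads was added as an alternative. Comparisons with Uninjured were fitted within each pair's table on its own scale. HDAC5AA and HDAC5DAD against GFP and against each other were fitted on the recovered reads of the 15 libraries joined, scaled by median-of-ratios size factors. The fit was limma-trend with robust empirical Bayes on log2(value + 1), for genes with a mean of at least 1, with two-sided tests and Benjamini-Hochberg adjusted p under 0.05. The edgeR test (quasi-likelihood, TMM, filterByExpr) on recovered reads gave 1072 genes higher and 1069 lower in GFP, 1003 and 604 in HDAC5AA, and 1447 and 1021 in HDAC5DAD against Uninjured. Log2 fold changes are given with their standard error, levels as mean ± SD of normalized reads. Where a group held 1 to 3 reads of a gene over its libraries, a ratio of pooled normalized reads with an exact 95% interval was given instead.

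Results for some single genes are not reported here. Members of 32 lists were tested together with limma camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over the 32 lists of a comparison. The lists were genes of retinal ganglion cells, regeneration and axon growth, the integrated stress response, cell death, reactive and resting Mueller glia, astrocytes and optic nerve glia, microglia, activated microglia and myeloid cells, lymphocytes, interferon response, MHC class I antigen presentation, complement, rods, cones, bipolar, amacrine, horizontal and vascular cells, retinal pigment epithelium, lens, ciliary body with iris and cornea, blood, immediate early and MEF2-linked activity, class IIa HDACs and MEF2, mTOR, cholesterol synthesis, cell cycle, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear retained RNA and sex-linked genes. Lists share members, such as Stat3 in the regeneration and reactive Mueller glia lists and Psmb8 and Psmb9 in the interferon and MHC class I lists. They are therefore not independent, and in whole retina a change of a list does not show which cells it came from. The score of a list in a library was the mean log2 value of its genes, compared between injured groups by exact permutation. Genes were named by a rule, with Hdac5 first. Per comparison, up to 8 largest rises and falls followed, among genes that passed, with a named symbol and no overlap between the libraries of the groups. Their mean of log2(value + 1) had to be at least 1, where the rule as written beforehand named the log2 CPM scale. The bar used is lower, so genes with few reads could be named. Up to 4 members of each list with the smallest p were named as well. So were the 10 members of the deposited HDAC5AA list with the smallest p in HDAC5AA against GFP.

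Alternatives were other scaling (TMM), filters on low values, pseudocounts of 0.1 and 5, DESeq2, other libraries in the fit, the replicate number as a block, a fold threshold, leaving out each library, and, added after seeing the data, edgeR, the class of ribosomal RNA reads (under or at least 1%) as a covariate or a filter, and a mean of at least 10. The limma, edgeR and list tests were first run on simulated counts with the dispersion of each gene, with 100 genes changed 2-fold and 100 changed 1.5-fold among genes with a mean of at least 20, in 5 draws per comparison. For GFP against Uninjured, over 19961 genes, limma recovered 90.6% of the 2-fold and 73.0% of the 1.5-fold changes, and 7.04% of its calls were unchanged genes. For HDAC5AA against HDAC5DAD, over 19495 genes, the values were 92.4%, 74.8% and 5.19%. R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.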

Results

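Whole retinas of C57BL/6 mice aged around 6 weeks were profiled by RNA sequencing in 4 groups. Retinas of 3 groups had received an adeno-associated virus (AAV2) in the vitreous, the gel that fills the eye, carrying GFP, HDAC5AA or HDAC5DAD. The optic nerve, which holds the axons of the retinal ganglion cells, was crushed 2 weeks later with a hold of 3 seconds, at around 1 mm from the back of the eye, and the retinas were taken 4 days after that. The remaining group was uninjured retina, for which the labels name no virus. HDAC5 is a class IIa histone deacetylase, and the labels do not say which changes AA and DAD mark. Uninjured, HDAC5AA and HDAC5DAD had 4 libraries each and GFP had 3, since GFP replicate 1 was not analysed here. The title of the series names axon growth genes and both HDAC5 forms.

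The reads recovered per library ranged from 10939457 in HDAC5AA replicate 4 to 30970658 in Uninjured replicate 3. Features that hold ribosomal RNA sequence (Lars2, Gm15564, CT010467.1, Mir6236, Gm25732, Gm23935 and mt-Rnr1) took 0.0212% to 9.87% of these reads. The share lay under 1% in 6 libraries (Uninjured replicates 2 and 3, HDAC5AA replicates 1 and 2, HDAC5DAD replicates 2 and 3) and at or over 1% in the other 9, all 3 GFP libraries among them. The first principal component of log2 normalized counts held 35.3% of the variance, of which the 4 groups accounted for 96.4%. The second held 9.55%, of which the ribosomal RNA class accounted for 54.7% and the groups for 6.79%. Nothing in the labels says that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

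Hdac5 (ENSMUSG00000008855, chromosome 11, 102194432 to 102230166, minus strand; protein coding), the gene of the deacetylase under study, was measured first in every library, on counts normalized jointly over the 15 libraries. The uninjured libraries held 6593, 6959, 6871 and 6920.5 normalized reads, and GFP replicates 2 to 4 held 6566, 6613 and 6673. HDAC5DAD replicates 1 to 4 held 8634, 7467, 7543 and 8423, and HDAC5AA replicates 1 to 4 held 7474, 8065, 8444 and 6694. The group means were 6836 ± 166 (SD, n = 4), 6617 ± 53.8 (n = 3), 8017 ± 598 (n = 4) and 7669 ± 763 (n = 4) in Uninjured, GFP, HDAC5DAD and HDAC5AA. Against Uninjured, Hdac5 rose in HDAC5DAD, with a log2 fold change of 0.23 (SE 0.05) and a limma Benjamini-Hochberg adjusted p = 0.00766. The values were 0.16 (SE 0.06) and adjusted p = 0.130 in HDAC5AA, and -0.05 (SE 0.05) and adjusted p = 0.616 in GFP. Without HDAC5AA replicate 4, the library with the fewest reads, the HDAC5AA value was 0.22 with adjusted p = 0.0113. Against GFP, every HDAC5AA and HDAC5DAD library lay above every GFP library, with log2 fold changes of 0.21 (SE 0.07) and 0.27 (SE 0.07), but neither passed in limma (adjusted p = 0.737 and 0.154). DESeq2, run as an alternative on the recovered reads, gave adjusted p = 0.0296 for HDAC5DAD against GFP. Reads of the virus transcript cannot be told from those of the mouse gene in these counts.

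**Figure D1:**
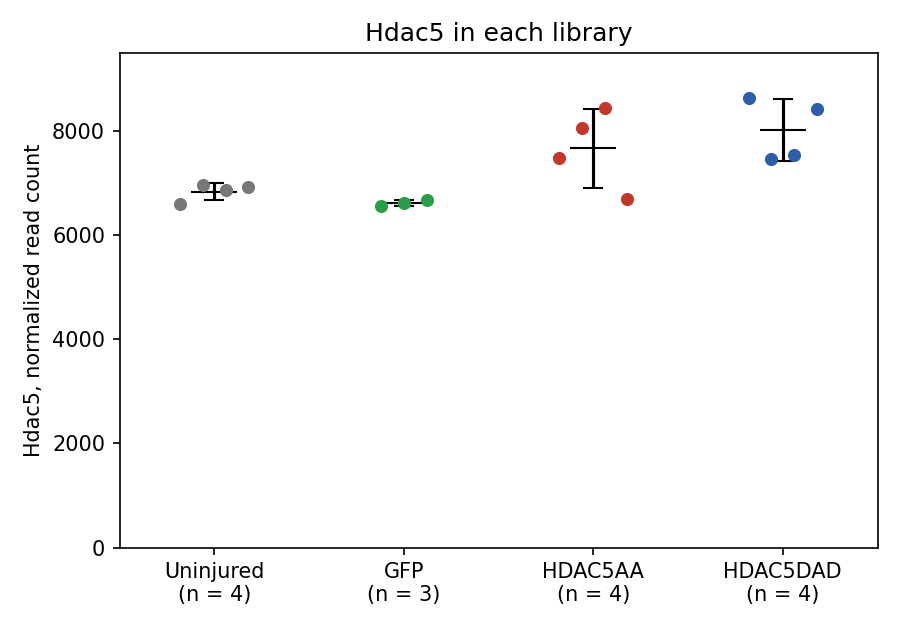
Hdac5 in each library, as jointly normalized read counts on a linear axis that starts at 0. Points are libraries, black bars are group means with SD (GFP n = 3, other groups n = 4). The HDAC5AA libraries lie between 6694 and 8444 and the HDAC5DAD libraries between 7467 and 8634, above the 3 GFP libraries.

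GFP against Uninjured showed what virus and nerve crush changed together, since the uninjured retinas had neither a crush nor a named virus. Ecel1 (ENSMUSG00000026247, chromosome 1, 87147655 to 87156521, minus strand; protein coding), which encodes a membrane endopeptidase induced in damaged neurons, was at 1529 ± 122 (SD, n = 3) against 13.8 ± 2.91 (n = 4) normalized reads, a log2 fold change of 6.71 (SE 0.15) with limma adjusted p = 3.92e-17. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, plus strand; protein coding), the macrophage elastase, rose by 7.26 (SE 0.74) to 584 ± 31.8 normalized reads, with limma adjusted p = 0.00236. Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966, plus strand; immunoglobulin constant gene), the kappa light chain constant region, was at 1291 ± 430.2 against 6.40 ± 2.02, a log2 fold change of 7.44 (SE 0.25). The heavy chain genes Ighg2b and Igha rose by 7.75 and 7.03 on the log2 scale, to 820.4 ± 596 and 617 ± 249. For genes with 1 to 3 reads over the 4 uninjured libraries a ratio of pooled normalized reads was taken. It was 202 (95% counting interval 55.5 to 1680.2) for Sprr1a, a regeneration-associated small proline-rich protein, 190.4 (95% counting interval 64.6 to 927) for Igkv6-32 and 369 (95% counting interval 65.5 to 14619) for Ighv1-52. Intervals and floors here cover counting error only. Immunoglobulin segments are near-identical copies, so how their reads were split between copies is uncertain.

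Among the falls in GFP, Scn4b (ENSMUSG00000046480, chromosome 9, 45138395 to 45154152, plus strand; protein coding), a sodium channel beta subunit, was at 12.3 ± 2.50 (SD, n = 3) against 167 ± 16.8 (n = 4) normalized reads, a log2 fold change of -3.66 (SE 0.17) with limma adjusted p = 1.68e-11. Pou4f2 (ENSMUSG00000031688, chromosome 8, 78433010 to 78436645, minus strand; protein coding), a transcription factor of retinal ganglion cells, was at 21.97 ± 4.29 against 148 ± 17.0, a log2 fold change of -2.71 (SE 0.17). Pvalb, which encodes the calcium-binding protein parvalbumin, was at 48.6 ± 4.57 against 269 ± 9.16 (-2.45), and Tusc5, a regulator of glucose transporter trafficking, at 142 ± 24.4 against 779 ± 58.3 (-2.46). Ctxn3 (a small membrane protein of the cortexin family), Irx4 (a homeobox transcription factor), Ppp1r1c (a protein phosphatase inhibitor subunit) and Prokr1 (a prokineticin receptor) fell, with log2 fold changes of -3.33, -3.16, -3.25 and -3.14. In limma, 1112 of 19961 genes were higher and 1164 lower in GFP. Of these, 453 and 91 changed by a log2 fold change of at least 1. The libraries of the 2 groups did not overlap for 4363 genes (21.9%), where chance gives 5.71%. Among libraries with at least 1% ribosomal RNA reads, a choice made after seeing the data, 799 genes were higher and 772 lower.

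Of the retinal ganglion cell genes, 30 of 42 measured fell in GFP and 1 rose (37 and 1 adjusted over the list alone), with a median log2 fold change of -0.80 (limma camera adjusted p = 1.80e-38, and adjusted p = 0.0286 with an estimated correlation). Chrna6, a nicotinic receptor subunit, was at 929.5 ± 54.8 against 2609 ± 134, Tppp3, a tubulin-binding protein, at 629.9 ± 39.0 against 1949.7 ± 87.5 and the transcription factor Pou4f1 at 190.0 ± 25.5 against 604 ± 15.9 normalized reads. Of the regeneration-associated and axon growth genes, 31 of 53 rose and 2 fell (33 and 3 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 9.59e-21, and adjusted p = 0.00286 with an estimated correlation). The stress transcription factor Atf3 was at 1364 ± 120.0 against 197 ± 22.5, the TWEAK receptor gene Tnfrsf12a at 666 ± 62.7 against 163 ± 24.8 and the cytokine signal transducer Stat3 at 4171 ± 189.9 against 1962 ± 169. Of the integrated stress response genes, 23 of 30 rose (23 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 7.95e-26, and adjusted p = 0.00286 with an estimated correlation). Chac1, a glutathione-degrading enzyme, was at 223 ± 18.0 against 32.9 ± 3.61 and Mthfd2, of mitochondrial folate metabolism, at 408 ± 20.5 against 149.8 ± 4.41. Of the cell death genes, 10 of 21 rose (12 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 1.54e-08, and adjusted p = 0.0147 with an estimated correlation). The BH3-only gene Hrk was at 211 ± 7.90 against 45.2 ± 4.80 and the cell cycle inhibitor Cdkn1a at 41.9 ± 6.68 against 10.0 ± 3.76.

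Glial and immune genes rose as well in GFP. Of the reactive Mueller glia genes, 26 of 32 rose (29 adjusted over the list alone), with a median of 1.46 (limma camera adjusted p = 3.98e-35, and adjusted p = 0.0191 with an estimated correlation). The oncostatin M receptor gene Osmr was at 727 ± 109.8 against 219 ± 24.5 and the hyaluronan receptor gene Cd44 at 627 ± 122 against 226 ± 15.3. Of the microglia genes 16 of 22 rose (17 adjusted over the list alone; median 1.00; camera adjusted p = 3.05e-20, and adjusted p = 0.0191 with an estimated correlation). The lysosomal protease gene Ctss was at 951 ± 167 against 258 ± 22.6 and the complement gene C1qa at 588 ± 109 against 146 ± 18.5. Of the activated microglia and myeloid cell genes 26 of 29 rose (28 adjusted over the list alone), with a median of 2.07 (camera adjusted p = 1.24e-29, and adjusted p = 0.0334 with an estimated correlation). Cd68, a lysosomal membrane protein of macrophages, was at 156 ± 25.8 against 49.8 ± 7.64. Of the interferon response genes 44 of 48 rose (46 adjusted over the list alone), with a median of 1.42 (camera adjusted p = 7.45e-48, and adjusted p = 0.0147 with an estimated correlation). Ifit1 was at 278 ± 40.2 against 66.0 ± 9.36, the interferon-inducible GTPase gene Irgm1 at 301 ± 46.0 against 84.7 ± 10.96 and the transcription factor gene Irf9 at 913 ± 86.9 against 401 ± 15.95. Of the MHC class I antigen presentation genes 16 of 20 rose (17 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 3.05e-20, and adjusted p = 0.0383 with an estimated correlation). B2m was at 1841 ± 309 against 496 ± 43.9 and the transactivator gene Nlrc5 at 165 ± 39.4 against 20.7 ± 3.43. Complement genes rose in 9 of 17 cases (11 adjusted over the list alone), with a median of 1.57 (camera adjusted p = 4.08e-12, and adjusted p = 0.0404 with an estimated correlation). Lymphocyte genes rose in 7 of 12 (9 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 2.31e-09, and adjusted p = 0.0304 with an estimated correlation). Jchain, which joins antibody polymers, was at 478 ± 100.7 against 137 ± 22.5.

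HDAC5AA against Uninjured set the same crush, with HDAC5AA virus, against uninjured retina. The genes with the largest changes were mostly those named for GFP. Ecel1 was at 1804 ± 145 (SD, n = 4) against 12.6 ± 2.66 (n = 4) normalized reads, a log2 fold change of 7.07 (SE 0.13) with limma adjusted p = 3.12e-18, and Mmp12 at 633 ± 58.0 against 3.43 ± 2.37, a log2 fold change of 7.45 (SE 0.60). Ighg2b, Igkc, Igha and Ighg1, an immunoglobulin heavy chain gene, rose by 7.72, 7.41, 7.39 and 6.83 on the log2 scale, Ighg1 to 320.2 ± 284 and Igkc to 1325 ± 954 normalized reads. The ratio of pooled reads was 295 (95% counting interval 81.3 to 2446) for Sprr1a and 379 (95% counting interval 129 to 1839) for Igkv6-32. Scn4b fell to 8.95 ± 1.72 against 153 ± 15.4, a log2 fold change of -3.96 (SE 0.18), and Ctxn3, Irx4, Tusc5 and the serotonin receptor gene Htr1b fell too, with log2 fold changes of -3.20, -2.80, -2.35 and -2.30. Ppp1r1c, with 1 read over the 4 HDAC5AA libraries, had a ratio of 0.0108 (95% counting interval 0.000271 to 0.0614), and Serpinb1b, a serine protease inhibitor with 3 reads, one of 0.0520 (95% counting interval 0.0105 to 0.158). Pou4f2 was at 16.5 ± 12.5 against 136 ± 15.3, a log2 fold change of -3.40 (SE 0.74) with limma adjusted p = 0.0407, which rose to between 0.0965 and 0.109 without HDAC5AA replicate 2 or 3 or any 1 of the 4 uninjured libraries (log2 fold changes of -3.34 to -3.53). Its call was also lost with a pseudocount of 0.1 (-3.57, adjusted p = 0.0601), with the replicate number as a block (-3.40, adjusted p = 0.0719) and among the libraries with at least 1% ribosomal RNA reads (-4.21, adjusted p = 0.268). In limma 1060 of 19714 genes were higher and 625 lower, of which 469 and 77 had a log2 fold change of at least 1 in size. Among the libraries with at least 1% ribosomal RNA reads, with fewer libraries per group, 500 genes were higher and 363 lower.

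In HDAC5AA, 28 of 42 retinal ganglion cell genes fell and 1 rose (33 and 2 adjusted over the list alone), with a median log2 fold change of -0.65 (limma camera adjusted p = 3.08e-40, and adjusted p = 0.0112 with an estimated correlation). Chrna6 was at 868 ± 36.1 against 2393 ± 125 and the gamma-synuclein gene Sncg at 561 ± 50.0 against 1598 ± 115. Of the regeneration-associated and axon growth genes 29 of 53 rose (34 rose and 1 fell adjusted over the list alone), with a median of 0.69 (camera adjusted p = 4.90e-29, and adjusted p = 0.0103 with an estimated correlation). Atf3 was at 1142 ± 84.6 against 181 ± 20.6 and Sox11, a transcription factor of growing neurons, at 906 ± 63.2 against 100.4 ± 22.8. Integrated stress response genes rose in 24 of 30 (27 adjusted over the list alone; median 0.56; camera adjusted p = 1.47e-34, and adjusted p = 0.00918 with an estimated correlation). Chac1 was at 250.0 ± 28.1 against 30.2 ± 3.37 and the serine synthesis gene Phgdh at 97.4 ± 16.7 against 19.9 ± 2.71. Cell death genes rose in 12 of 22 and fell in 1 (13 and 1 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 2.52e-10, and adjusted p = 0.0103 with an estimated correlation). Reactive Mueller glia genes rose in 27 of 32 (29 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 4.73e-39, and adjusted p = 0.0127 with an estimated correlation). Microglia genes rose in 16 of 22 (20 adjusted over the list alone), with a median of 1.20 (camera adjusted p = 3.11e-25, and adjusted p = 0.0481 with an estimated correlation).

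Immune lists rose in HDAC5AA too. Of the activated microglia and myeloid cell genes 28 of 32 rose (30 adjusted over the list alone), with a median of 2.43 (limma camera adjusted p = 1.32e-42, and adjusted p = 0.0124 with an estimated correlation). Mpeg1, a macrophage pore-forming protein, was at 231 ± 46.5 against 52.3 ± 11.05. Interferon response genes rose in 41 of 48 (47 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 1.14e-54, and adjusted p = 0.0112 with an estimated correlation). MHC class I antigen presentation genes rose in 16 of 20 (18 adjusted over the list alone), with a median of 1.65 (camera adjusted p = 5.76e-29, and adjusted p = 0.0323 with an estimated correlation). Irf9 was at 783 ± 61.2 against 368 ± 15.1 and the MHC class I gene H2-D1 at 1646 ± 287 against 614 ± 30.7. Complement genes rose in 11 of 17 (12 adjusted over the list alone; median 1.79; camera adjusted p = 2.21e-16, and adjusted p = 0.0320 with an estimated correlation). Lymphocyte genes rose in 9 of 16 (12 adjusted over the list alone; median 1.61; camera adjusted p = 3.39e-14, and adjusted p = 0.0159 with an estimated correlation).

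HDAC5DAD against Uninjured had the largest number of calls of the 3 comparisons with uninjured retina. Ecel1 was at 1924 ± 213 (SD, n = 4) against 13.6 ± 2.88 (n = 4) normalized reads, a log2 fold change of 7.05 (SE 0.13) with limma adjusted p = 1.00e-17, and Mmp12 at 708 ± 52.7 against 3.70 ± 2.56, a log2 fold change of 7.55 (SE 0.63). Ighg1 was at 897 ± 477 against 1.23 ± 1.11 (8.63, SE 0.54), and Ighg2b, Igkc and Igha rose by 8.26, 8.11 and 7.99 on the log2 scale, to 1165 ± 1017, 2362 ± 1772 and 1578 ± 1316. Single HDAC5DAD libraries spanned 641 to 2690 for Ighg2b, 1148 to 4934 for Igkc and 313 to 3347 for Igha, so high libraries weigh on these means. The ratio of pooled reads was 467 (95% counting interval 159.6 to 2269.6) for Igkv6-32 and 797 (95% counting interval 143 to 31528) for Ighv1-52. Scn4b was at 9.69 ± 3.70 against 165 ± 16.7 (-4.02, SE 0.22) and Pou4f2 at 18.7 ± 4.66 against 147 ± 16.7 (-2.93, SE 0.18). Ctxn3, Irx4, Serpinb1b, the orphan receptor gene Gpr101 and the homeobox gene Irx1 fell, with log2 fold changes of -2.94, -2.66, -2.89, -2.54 and -2.44, and Ppp1r1c, with 1 read over the 4 HDAC5DAD libraries, had a ratio of 0.00954 (95% counting interval 0.000240 to 0.0542). In limma 1556 of 19956 genes were higher and 1091 lower, of which 651 and 86 had a log2 fold change of at least 1 in size. Among the libraries with at least 1% ribosomal RNA reads 1000 genes were higher and 947 lower. With fewer libraries Mmp12 kept its change there but not its call, with log2 fold changes of 8.15 in HDAC5DAD (adjusted p = 0.0804) and 8.09 in HDAC5AA (adjusted p = 0.0697).

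In HDAC5DAD, 34 of 42 retinal ganglion cell genes fell and 1 rose (35 and 1 adjusted over the list alone), with a median of -0.66 (limma camera adjusted p = 1.55e-37, and adjusted p = 0.0270 with an estimated correlation). Sncg was at 571 ± 46.3 against 1725 ± 125 and the sodium channel gene Scn1a at 949 ± 18.5 against 2176 ± 223. Regeneration-associated and axon growth genes rose in 33 of 53 and fell in 2 (36 and 2 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 3.99e-25, and adjusted p = 0.0169 with an estimated correlation). Atf3 was at 1315 ± 112 against 195 ± 22.3 and Tnfrsf12a at 686 ± 43.7 against 161 ± 24.5. Integrated stress response genes rose in 25 of 30 (27 adjusted over the list alone; median 0.58; camera adjusted p = 1.30e-29, and adjusted p = 0.00450 with an estimated correlation). The transcription factor gene Ddit3 was at 1857 ± 112 against 1009 ± 49.3. Cell death genes rose in 14 of 23 (14 rose and 1 fell adjusted over the list alone; median 0.69; camera adjusted p = 9.93e-11, and adjusted p = 0.00530 with an estimated correlation). Reactive Mueller glia genes rose in 29 of 32 (30 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 1.55e-37, and adjusted p = 0.0203 with an estimated correlation). The GTPase gene Gbp2 was at 845 ± 73.1 against 79.2 ± 18.5.

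Immune genes rose in HDAC5DAD in each of the 6 immune lists. Microglia genes rose in 19 of 22 (20 adjusted over the list alone; median 1.18; limma camera adjusted p = 6.97e-26, and adjusted p = 0.0224 with an estimated correlation). Activated microglia and myeloid cell genes rose in 30 of 31 (30 adjusted over the list alone; median 3.13; camera adjusted p = 1.25e-37, and adjusted p = 0.0203 with an estimated correlation). C1qb was at 640.1 ± 118 against 123 ± 19.3 and Tlr2, a receptor for bacterial products, at 82.4 ± 23.6 against 8.36 ± 1.70. Interferon response genes rose in 44 of 48 (47 adjusted over the list alone), with a median of 1.85 (camera adjusted p = 4.78e-55, and adjusted p = 0.0182 with an estimated correlation). The transcription factor gene Irf1 was at 579 ± 56.5 against 138 ± 13.6 and the GTPase gene Iigp1 at 227 ± 37.8 against 13.0 ± 4.80. MHC class I antigen presentation genes rose in 18 of 20 (19 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 2.65e-31, and adjusted p = 0.0103 with an estimated correlation). The peptide transporter gene Tap1 was at 449 ± 86.3 against 82.6 ± 6.86. Complement genes rose in 12 of 17 (12 adjusted over the list alone; median 1.71; camera adjusted p = 1.19e-15, and adjusted p = 0.0270 with an estimated correlation). Lymphocyte genes rose in 15 of 19 (15 adjusted over the list alone), with a median of 2.47 (camera adjusted p = 5.41e-16, and adjusted p = 0.0916 with an estimated correlation). Fewer members were measured in the other injured groups, so their medians are not over the same genes. Over the lymphocyte genes measured in all 3 tables, the mean score above Uninjured was 2.44 in HDAC5DAD, 1.86 in HDAC5AA and 1.90 in GFP. The list holds Jchain and also Igkc, which rose by 8.11, 7.41 and 7.44 on the log2 scale in these groups. Its score is therefore not separate from the rise of immunoglobulin genes. The T cell kinase gene Lck was at 50.2 ± 4.44 against 18.1 ± 3.53.

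**Figure D2:**
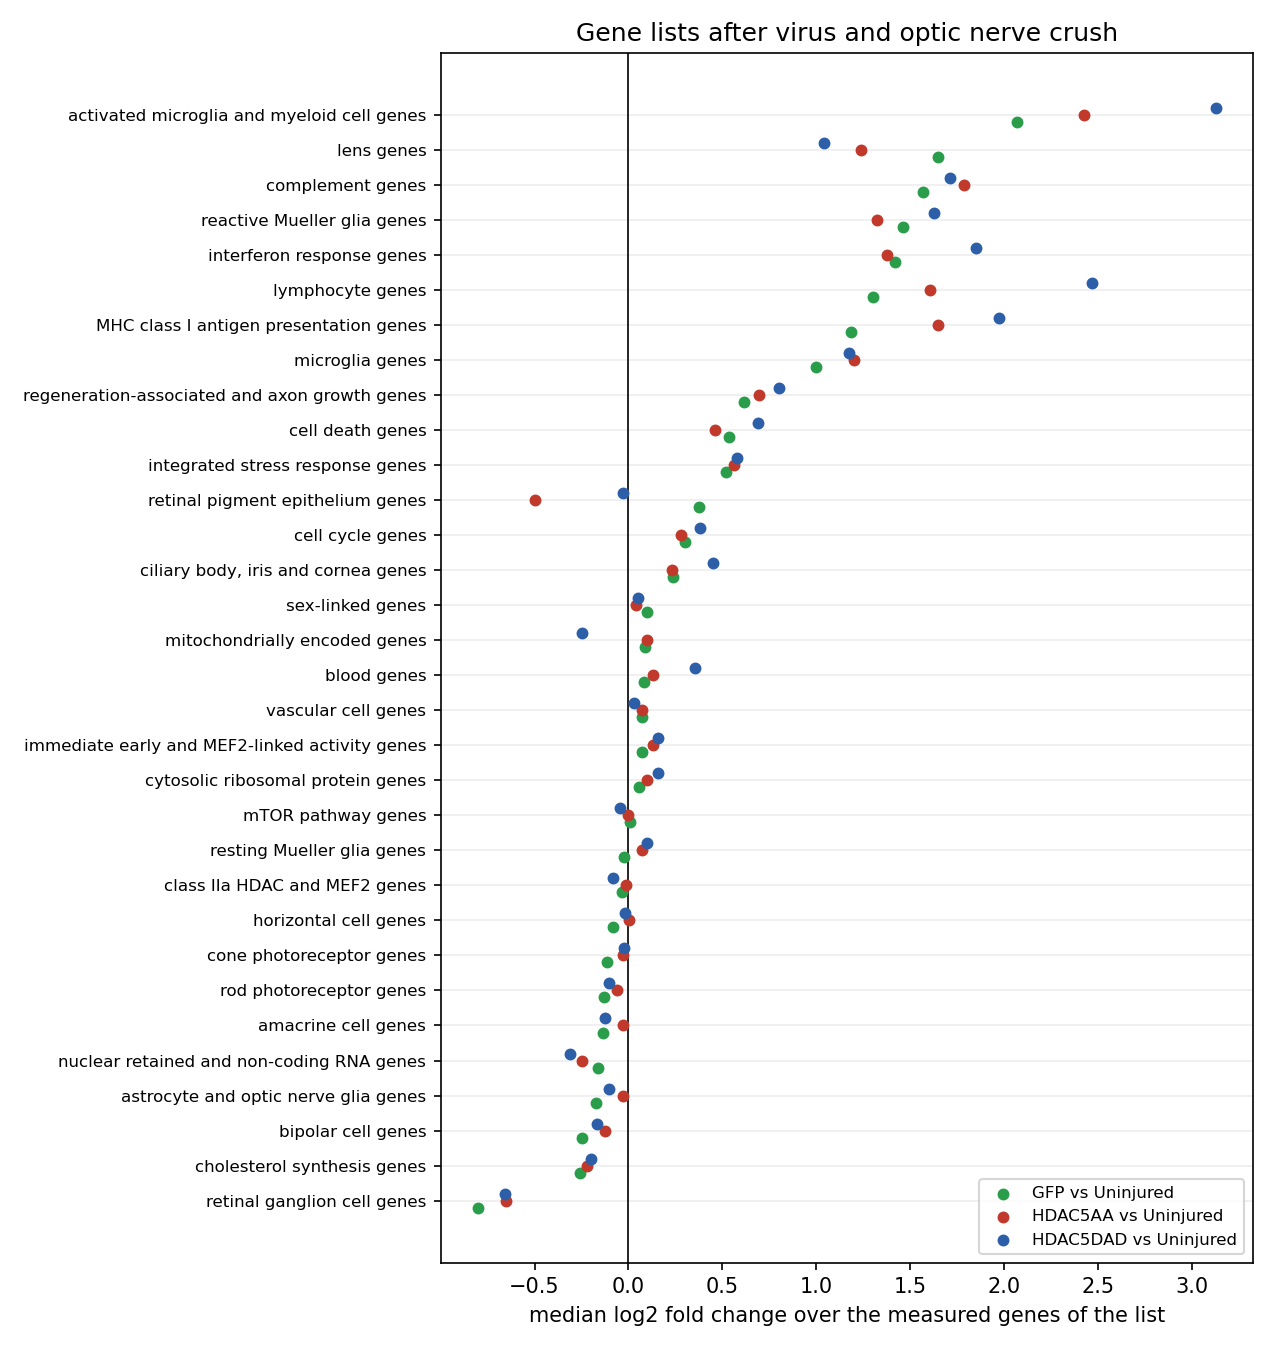
Median log2 fold change against Uninjured of the measured members of each of the 32 gene lists, on a linear log2 axis, with lists ordered by the GFP value. Points are GFP, HDAC5AA and HDAC5DAD, each a median over genes without an error bar. The retinal ganglion cell list lies at -0.80, -0.65 and -0.66, and the activated microglia and myeloid cell list at 2.07, 2.43 and 3.13. The members measured can differ between the groups, as in the latter list, so such medians are not over the same genes. Over the members measured in all 3 tables, the mean scores of the latter list were 2.25, 2.47 and 2.83 above Uninjured.

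Genes of the other retinal neurons had list medians between -0.25 and 0.00 on the log2 scale. Bipolar cell genes fell in 11 of 22 in GFP, 3 in HDAC5AA and 6 in HDAC5DAD (11, 6 and 9 adjusted over the list alone), with medians of -0.25, -0.13 and -0.17 (limma camera with an estimated correlation, adjusted p = 0.0434, 0.117 and 0.0947). Pcp2, a modulator of G protein signalling in these cells, was at 1279.8 ± 109 against 1695 ± 124 in GFP, and the receptor gene Gpr179 at 4333 ± 298 against 5514 ± 271 in HDAC5DAD. Rod genes fell in 6 of 26, 2 and 5 and rose in 1, 1 and 2. Pdc, which encodes phosducin, was at 26667 ± 4524 in GFP against 45178 ± 2771. Cone genes fell in 4 of 15, 2 and 2 and rose in 1 each, Gnb3, a G protein subunit gene, by 0.55, 0.47 and 0.73. Amacrine cell genes fell in 3 of 25, 1 and 6, the last beside 1 that rose. The transcription factor gene Pax6 fell in all 3 (-0.29, -0.24 and -0.26). Horizontal cell genes fell in 1 of 11 in each group, which was the calcium-binding gene Calb1 (-0.46, -0.29 and -0.30). With an estimated correlation none of the rod, cone, amacrine or horizontal lists passed in any of the 3 groups, the lowest adjusted p being 0.311.

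Other glial and vascular lists moved both ways or little. Of 19 resting Mueller glia genes 3, 3 and 6 rose in GFP, HDAC5AA and HDAC5DAD and 4 fell in each, the glutamine synthetase gene Glul among the latter (-0.51, -0.46 and -0.40). Of 9 astrocyte and optic nerve glia genes 1 rose in each group, Aldh1l1, a folate enzyme of astrocytes, by 0.39, 0.38 and 0.56, and 1, 1 and 0 fell. Of 21 vascular cell genes 1, 4 and 5 rose and 0, 0 and 1 fell. Vwf, the von Willebrand factor gene, was at 831 ± 149 against 335 ± 54.7 in GFP. Limma camera with an estimated correlation gave adjusted p of at least 0.143 for these 3 lists in each group.

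Lists of neighbouring tissues were measured for material left on the retinas. Of the retinal pigment epithelium genes 0 of 15 passed in GFP, 0 of 14 in HDAC5DAD, and 1 of 14 fell in HDAC5AA, the melanosome gene Pmel (ENSMUSG00000025359, chromosome 10, 128704195 to 128720238, plus strand; protein coding) at 18.9 ± 8.45 against 42.6 ± 7.74 (limma adjusted p = 0.00630). Pmel was at 121 ± 115 in GFP and 41.4 ± 20.6 in HDAC5DAD. Its HDAC5AA call was lost when all 15 libraries shared a fit (adjusted p = 0.267), at a log2 fold change of -1.22 against -1.22 in its own table. It was lost too in DESeq2 (-1.16, adjusted p = 0.278), with the ribosomal RNA class as a covariate (-1.22, adjusted p = 0.305) and among the libraries with at least 1% ribosomal RNA reads (-0.999, adjusted p = 0.167). Lens genes rose in 3 of 14 in GFP, 4 of 11 in HDAC5AA and 2 of 11 in HDAC5DAD, the crystallin gene Crybb1 by 1.21, 1.24 and 0.96. Genes of ciliary body, iris and cornea rose in 1 of 8, 0 of 7 and 2 of 7, the collagen gene Col3a1 at 136 ± 55.8 against 55.1 ± 6.41 in HDAC5DAD. Of the 5 blood genes 0 rose and 0 fell in any group, with the haemoglobin gene Hbb-bt at 30.8 ± 7.05 against 27.3 ± 10.2 in GFP. With an estimated correlation limma camera passed none of these 4 lists in any group (lowest adjusted p = 0.127).

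Of the metabolic and regulatory lists, cholesterol synthesis genes fell in 10 of 22, 9 and 10 in GFP, HDAC5AA and HDAC5DAD (14, 15 and 13 adjusted over the list alone), with medians of -0.26, -0.22 and -0.20 (limma camera with an estimated correlation, adjusted p = 0.0147, 0.0103 and 0.0947). Cell cycle genes rose in 3 of 19, 3 of 20 and 6 of 20, the proliferation marker Mki67 at 25.3 ± 4.21 against 4.26 ± 2.07 in GFP (list adjusted p = 0.0383, 0.107 and 0.0947 with an estimated correlation). Immediate early and MEF2-linked activity genes rose in 6 of 29, 6 and 8 and fell in 1, 0 and 0, the transcription factor gene Jun by 0.68, 0.67 and 0.74. Class IIa HDAC and MEF2 genes fell in 2 of 15, 1 and 3 and rose in 1, 0 and 1, the kinase gene Camk2b falling (-0.35, -0.22 and -0.27). mTOR pathway genes rose in 2 of 39, 3 and 2 and fell in 0, 0 and 1. The members that rose include Sesn2, a stress-induced inhibitor of the pathway (0.64, 0.74 and 0.59), and Eif4ebp1, a repressor of translation (1.12, 1.08 and 1.20).

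Cytosolic ribosomal protein genes rose in 0 of 38, 4 and 10 in GFP, HDAC5AA and HDAC5DAD, Rps3 by 0.22 and 0.24 in the latter groups. Of 9 mitochondrially encoded genes 0 passed in limma in any of the 3 groups, with medians of 0.09, 0.10 and -0.25. Nuclear retained and non-coding RNA genes rose in 1 of 8, 1 and 0 and fell in 0, 2 and 0, with Neat1 at 626 ± 88.4 against 435 ± 54.9 in GFP. Of the 2 sex-linked genes measured, Xist rose in GFP by 0.21 (SE 0.06), and neither passed in HDAC5AA or HDAC5DAD. With an estimated correlation limma camera passed none of the immediate early, class IIa HDAC, mTOR, ribosomal protein, mitochondrial, non-coding and sex-linked lists in any of the 3 groups.

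Calls were shared between the injured groups beyond what chance gives. GFP and HDAC5AA shared 826 genes that rose and 543 that fell, where independent lists would share 58.1 and 37.1. GFP and HDAC5DAD shared 933 and 713 (independent, 82.5 and 64.4), and HDAC5AA and HDAC5DAD shared 981 and 523 (independent, 80.4 and 34.8). All 3 groups shared 799 genes that rose, Ecel1 and Mmp12 among them, and 490 that fell, Scn4b and Pou4f2 among them. The 3 comparisons share the uninjured libraries. In 50 simulations of unchanged groups against them at most 1 call was shared. Those groups had means of only 0.22 to 0.68 calls per direction, so the simulations cannot show how far shared libraries raise the overlap of long lists. With the uninjured libraries split into 2 and 2, so that the groups shared none, the mean numbers of shared calls were 535 and 304 for GFP and HDAC5AA, 617 and 396 for GFP and HDAC5DAD, and 623 and 279 for HDAC5AA and HDAC5DAD. In the authors' deposited tables, 984, 1052 and 1533 genes were higher in GFP, HDAC5AA and HDAC5DAD at their adjusted p under 0.05, of which 954, 1001 and 1472 were also limma calls.

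HDAC5AA against GFP compared 2 groups that both received crush and a virus, each virus with its own gene. HDAC5AA replicates 1 and 2 lay in the class under 1% of ribosomal RNA reads, where no GFP library lay. No gene passed: in limma 0 of 19495 genes were higher and 0 lower, in edgeR 0 and 0, and in DESeq2 0 and 0. At an unadjusted p under 0.05 limma gave 1284 genes, where chance gives about 974.8. The smallest limma adjusted p was 0.737. Of the 53 regeneration-associated and axon growth genes 0 passed (0 adjusted over the list alone), with a median log2 fold change of 0.06 (limma camera adjusted p = 0.234, and adjusted p = 0.812 with an estimated correlation). Their smallest p values belonged to Ecel1, at 1822 ± 145 against 1419 ± 114 normalized reads (0.36, SE 0.11), and Lgals1, which encodes galectin-1, at 321 ± 25.7 against 278 ± 12.1 (0.20, SE 0.09). Of the retinal ganglion cell genes 0 of 42 passed, with a median of 0.10 (camera adjusted p = 0.000663, and adjusted p = 0.809 with an estimated correlation). The calretinin gene Calb2 was at 3256 ± 222 against 2770.1 ± 313. Of the MHC class I antigen presentation genes 0 of 20 passed, with a median of 0.40 (camera adjusted p = 6.16e-09, and adjusted p = 0.671 with an estimated correlation). The immunoproteasome gene Psmb9 was at 132 ± 37.9 against 77.6 ± 18.0. The list's camera call was lost with the estimated correlation, and the difference of its score, 0.368, was 0.202 without HDAC5AA replicate 2. The retinal pigment epithelium list had a median of -0.64 (camera adjusted p = 1.83e-06, and adjusted p = 0.671 with an estimated correlation), with 0 of 14 members passing and 2 adjusted over the list alone. The difference of this list's score, -0.895, was -0.370 without GFP replicate 3 and -1.35 without GFP replicate 2. Dct, a melanin synthesis gene, was at 47.6 ± 18.5 against 290.5 ± 278, with a GFP mean of 129.9 without replicate 3. In simulations of this comparison limma recovered 73.0% of genes changed 1.5-fold and 91.6% of those changed 2-fold. Each draw held 100 genes of each kind, all with a mean of at least 20, which makes the adjusted threshold easier to reach. The simulations therefore do not show that such changes were absent here.

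HDAC5DAD against GFP had the same limits, with HDAC5DAD replicates 2 and 3 in the class under 1%. Among the fixed lists, those of interferon response and antigen presentation genes had the smallest camera p values and lay higher in HDAC5DAD, but both calls were lost with an estimated correlation (adjusted p = 0.373 for each). No gene passed in the limma fit of the 15 libraries. The immunoproteasome gene Psmb8 was at 267 ± 33.5 (SD, n = 4) against 138 ± 28.4 (n = 3) normalized reads (0.95, SE 0.19; limma adjusted p = 0.154). A second such gene, Psmb9, was at 157 ± 41.8 against 77.6 ± 18.0, the transcription factor gene Irf1 at 543 ± 53.3 against 353 ± 40.7, and the peptide transporter gene Tap2 at 243 ± 11.5 against 175 ± 20.5. In limma 0 of 19495 genes were higher and 0 lower, with 2238 at an unadjusted p under 0.05 (1287 higher, 951 lower), where chance gives about 974.8. In edgeR 1 gene was higher, and in DESeq2 44 were higher and 13 lower. With only the 2 groups in the fit limma gave 10 higher and 1 lower, and among the libraries with at least 1% ribosomal RNA reads 8 and 5. The edgeR call was Ighg1, at 840.0 mean normalized reads against 12.7, a gene named after its values were seen. Of the 44 DESeq2 calls, 9 were in the interferon or MHC class I lists, with DESeq2 adjusted p = 0.00325 for Psmb8 and 0.00879 for Irf1.

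Of the interferon response genes 0 of 48 passed between HDAC5DAD and GFP over all genes and 21 were higher adjusted over the list alone, with a median log2 fold change of 0.41 (limma camera adjusted p = 1.44e-18, and adjusted p = 0.373 with an estimated correlation). Of the MHC class I genes 0 of 20 passed over all genes and 11 were higher adjusted over the list alone, with a median of 0.58 (camera adjusted p = 2.17e-17, and adjusted p = 0.373 with an estimated correlation). The mean score of the interferon list per library was 2.02 ± 0.31 (SD, n = 4) in HDAC5DAD and 1.54 ± 0.15 (n = 3) in GFP above the uninjured mean, an exact two-sided permutation p = 0.0857 over 35 splits. For the MHC class I list the scores were 1.73 ± 0.19 and 1.15 ± 0.22 (exact p = 0.0286, the smallest that 4 against 3 libraries allow). Adjusted over the 32 lists, both exact permutation p values were 0.427. Within the libraries with at least 1% ribosomal RNA reads the interferon median was 0.28, and with that class as a covariate 0.36. Of the regeneration-associated and axon growth genes 0 of 53 passed and 1 was higher adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.00932, and adjusted p = 0.414 with an estimated correlation). Lgals1, which had the smallest p of the list, was at 353 ± 27.9 against 278 ± 12.1, and Ecel1 at 1802 ± 196 against 1419 ± 114. The activated microglia and myeloid cell list had a median of 0.60 (camera adjusted p = 2.00e-07, and adjusted p = 0.414 with an estimated correlation). The difference of its score, 0.578, was 0.332 without GFP replicate 2.

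HDAC5AA against HDAC5DAD compared the 2 HDAC5 forms directly, and 2 genes passed in limma, as many as 5 of 35 splits of the same 8 libraries gave, so that chance was not excluded. Prdm13 (ENSMUSG00000040478, chromosome 4, 21677480 to 21685963, minus strand; protein coding), a transcription factor of amacrine cells, was higher in HDAC5AA, at 900.4 ± 38.3 (SD, n = 4) against 704 ± 49.7 (n = 4) normalized reads, a log2 fold change of 0.36 (SE 0.06). Agtpbp1 (ENSMUSG00000021557, chromosome 13, 59445742 to 59585227, minus strand; protein coding), which encodes a carboxypeptidase that trims polyglutamate chains of tubulin, was lower, at 18948 ± 1026 against 23532 ± 1620.3 (-0.31, SE 0.05). Both had a limma adjusted p = 0.0447, with 1 gene higher and 1 lower of 19495, and 1322 at an unadjusted p under 0.05, where chance gives about 974.8. In edgeR 0 genes passed, with adjusted p = 0.140 and 0.250 for Prdm13 and Agtpbp1, and in DESeq2 2 were higher and 4 lower, both genes among them. With log2 fold changes of 0.35 to 0.36 and -0.31 to -0.32, both calls were lost with TMM scaling (adjusted p = 0.0556), a pseudocount of 0.1 (0.0509), only the 2 groups in the fit (0.0694), the replicate number as a block (0.0888) and a mean of at least 10 (0.0549). They were lost as well among the libraries with at least 1% ribosomal RNA reads (0.30, adjusted p = 0.365, and -0.26, adjusted p = 0.268). The Prdm13 call was lost without any 1 of HDAC5AA replicates 1 to 4 or HDAC5DAD replicates 1, 3 and 4 (log2 fold changes of 0.31 to 0.38; highest adjusted p = 0.258). That of Agtpbp1 was lost without any 1 of HDAC5AA replicates 2 to 4 or HDAC5DAD replicates 2 to 4 (log2 fold changes of -0.29 to -0.31; highest adjusted p = 0.296).

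Of the 53 regeneration-associated and axon growth genes 0 passed between HDAC5AA and HDAC5DAD (0 adjusted over the list alone), with a median log2 fold change of -0.04 (limma camera adjusted p = 0.0766, and adjusted p = 0.524 with an estimated correlation). The GTPase gene Rab13 was at 145 ± 7.75 against 179.7 ± 16.4 (-0.30, SE 0.10), the growth factor gene Igf1 at 409.5 ± 29.8 against 357 ± 25.4 (0.20, SE 0.08), and the median standard error over all genes was 0.11. Interferon response genes had a median of -0.39 (camera adjusted p = 9.78e-20, and adjusted p = 0.322 with an estimated correlation), with 0 of 48 passing and 5 lower in HDAC5AA adjusted over the list alone. Parp14 was at 319 ± 58.7 against 455 ± 75.6 and Trim30a at 94.8 ± 21.5 against 149 ± 28.3. The difference of the list's score was -0.40 (exact two-sided permutation p = 0.114), and its median was -0.38 among the libraries with at least 1% ribosomal RNA reads and -0.42 among the others. The mean scores of immune cell lists lay lower in HDAC5AA as well, by -0.579 for lymphocyte genes, -0.356 for activated microglia and myeloid cell genes and -0.191 for microglia genes (exact permutation p = 0.229, 0.286 and 0.314). The libraries of both groups overlapped in each of these lists, with lymphocyte scores of 1.57 to 2.49 in HDAC5AA and 1.59 to 3.21 in HDAC5DAD. The lymphocyte list holds Igkc and Jchain, so its score is not separate from the immunoglobulin genes. Reactive Mueller glia genes had a median of -0.36 (camera adjusted p = 2.21e-07, and adjusted p = 0.492 with an estimated correlation), with 0 of 32 passing. The difference of their score, -0.306, was -0.201 without HDAC5AA replicate 3. The ceruloplasmin gene Cp was at 4441 ± 526 against 5749 ± 785. The log2 fold changes of HDAC5AA and HDAC5DAD against GFP correlated over the 19495 genes with r = 0.640, and unchanged groups sharing the GFP libraries gave 0.569 (0.540 to 0.602 in 50 simulations). The covariance was 0.0399 beside a simulated 0.0285, a difference of 0.0113. Genes are not independent replicates, and with 3 GFP libraries no split left 2 in each part, so part of the excess may come from the shared libraries. The simulations also drew each gene alone and held no ribosomal RNA class. Both HDAC5 groups had libraries under 1% and GFP had none, so the excess cannot be parted from that class.

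**Figure D3:**
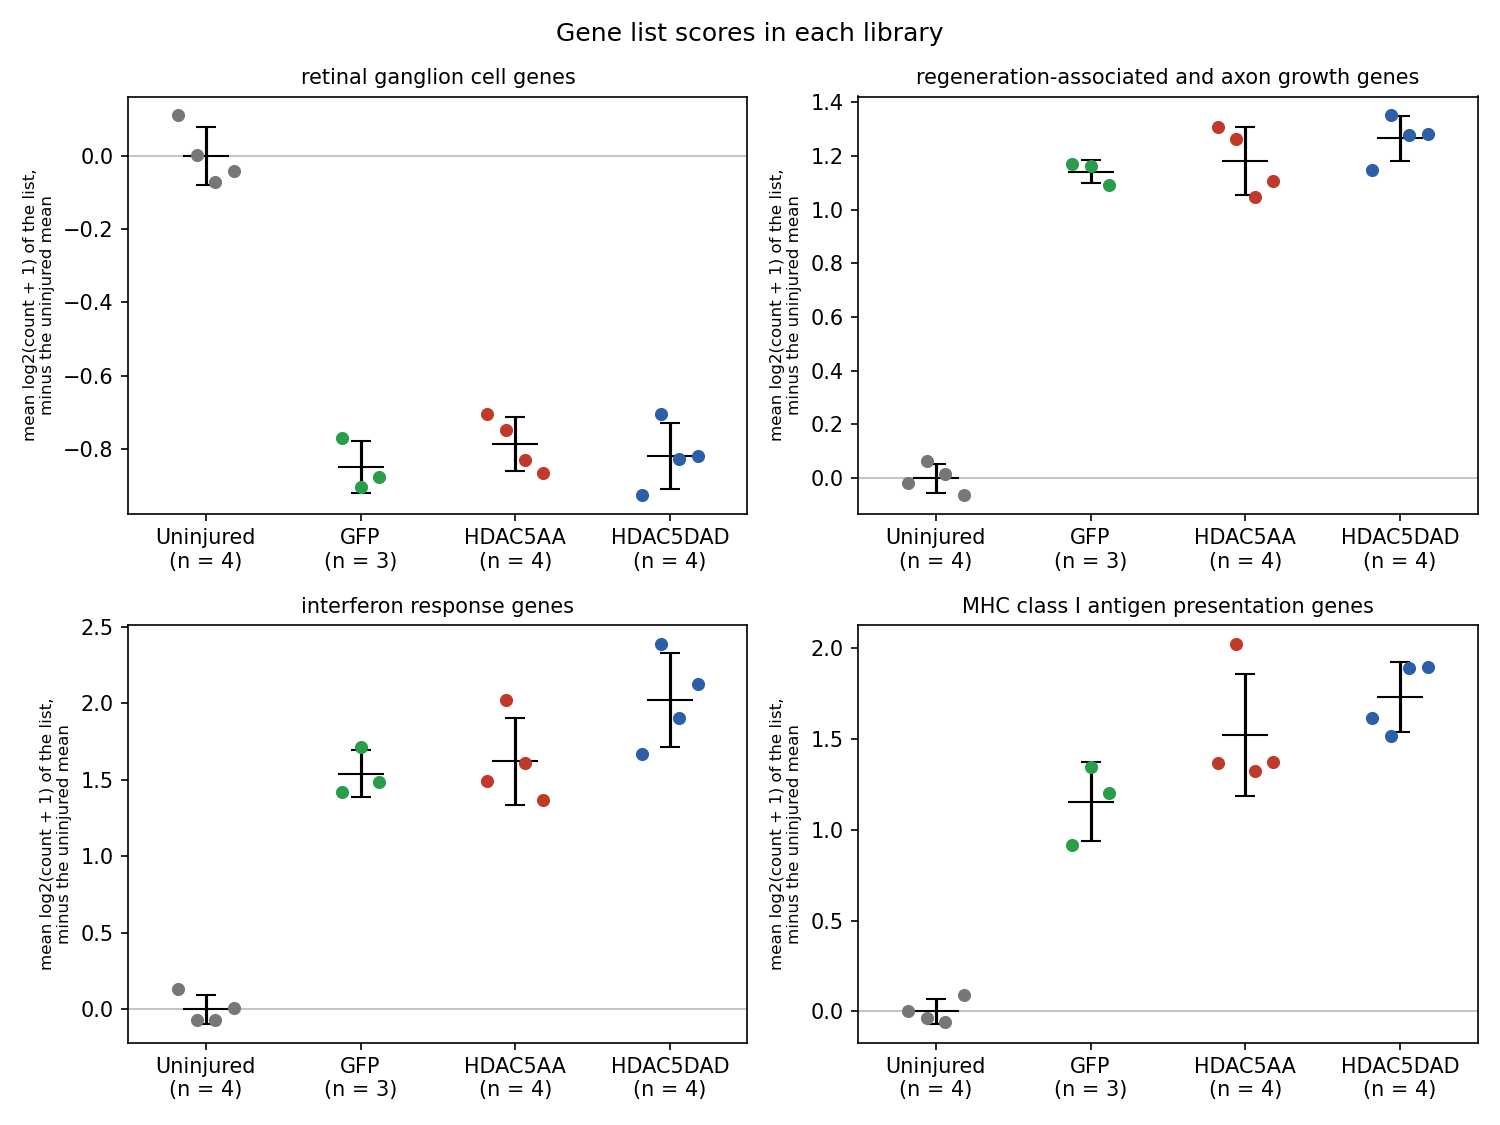
Score of 4 gene lists in each library, the mean log2(normalized count + 1) of the list's genes minus its uninjured mean, on linear axes. Points are libraries, black bars are group means with SD (GFP n = 3, other groups n = 4). The retinal ganglion cell scores of the injured groups lie between -0.93 and -0.70, and the interferon scores of HDAC5DAD between 1.67 and 2.39.

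A deposited list named as unique to HDAC5AA held 57 genes, which were exactly those lower with the authors' adjusted p under 0.1 in the HDAC5AA table and in neither other table. The study chose this list on these samples, so its direction is not independent evidence. In limma 29 of the 57 fell in HDAC5AA against Uninjured (56 adjusted over the list alone), with a median log2 fold change of -0.36. None passed in GFP or HDAC5DAD, where 51 and 57 of them lay below 0 and the medians were -0.22 and -0.24, with 25 and 22 lower at an unadjusted p under 0.05. Tested directly, 0 passed between HDAC5AA and GFP (1 adjusted over the list alone; 10 at an unadjusted p under 0.05), with a median of -0.13. Between HDAC5AA and HDAC5DAD 0 passed too (7 at an unadjusted p under 0.05), with a median of -0.14. Limma camera on the list gave p = 7.87e-12 for HDAC5AA against GFP, as an unadjusted value on genes chosen for being low, and p = 3.95e-05 with an estimated correlation. Among the 10 members with the smallest p in HDAC5AA against GFP were the melanin pathway genes Pmel, Tyr and Oca2, at 19.1 ± 8.53 against 112 ± 106, 9.43 ± 5.50 against 36.0 ± 25.8 and 6.78 ± 3.45 against 28.9 ± 25.2 normalized reads, and Gal3st1, a sulfotransferase gene, at 10.2 ± 2.47 against 16.9 ± 2.83. Without GFP replicate 3, the highest for all 3 melanin genes, their GFP means were 51.6, 21.1 and 15.2. The others were Tmem72 (-1.33), the antisense genes Pitpnm2os1 (-0.87), Gm17034 (-0.56) and Gm4419 (-0.40), and the long non-coding genes 4732414G09Rik (-0.51) and Gm2061 (-0.78), as log2 fold changes. The strand mode of counting was not stated, so it is not known whether reads of an antisense gene and its partner were told apart.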

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

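The tests of blood, of antibody-secreting cells, of residual ribosomal RNA reads, of immune cell number and of the MHC class I list were chosen after the results they bear on were seen, and the others before.

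Of 84 groups of 4 libraries tested for a library far from the other 3, 11 held one. The nominal chance rate of the test is about 5%, which does not hold for counts near 0. In HDAC5AA replicate 2 the score of the MHC class I list (2.02 above Uninjured) and that of the microglia list (1.67) lay far from the other HDAC5AA libraries, and in HDAC5DAD replicate 1 that of the reactive Mueller glia list (1.29). Among normalized counts, Ppp1r1c stood apart in HDAC5AA replicate 1 (0.904) and HDAC5DAD replicate 1 (1.52), Ctxn3 in HDAC5AA replicate 3 (15.9), Ighg2b in HDAC5DAD replicate 3 (2690.4), Igkv6-32 and Ighv1-52 in Uninjured replicate 3 (1.99 and 0.662), Sprr1a in Uninjured replicate 1 (2.48) and Pvalb in Uninjured replicate 3 (283). For Ppp1r1c, Igkv6-32, Ighv1-52 and Sprr1a these are counts of 1 to 3 reads, all in 1 library of the group. With 0 reads in the other libraries the test flags that library by construction. The 11 groups therefore do not show an excess of outlying libraries. Between the 2 HDAC5 forms Agtpbp1 (-0.31, HDAC5AA minus HDAC5DAD) and Prdm13 (0.36) passed in limma, each with adjusted p = 0.0447, but chance was not excluded (5 of 35 splits gave as many genes) and neither passed in edgeR, with TMM scaling or with only the 2 groups in the fit (adjusted p = 0.0694).

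Immunoglobulin features rose in every injured group: 24 of 28 in GFP, 23 of 33 in HDAC5AA and 42 of 55 in HDAC5DAD, and none fell. Each uninjured library held only 41 to 79 reads of the features measured in all 3 tables, and genes with few reads had been left out before deposit. A feature was thus measured mainly where the injured group had reads. The absence of falls was therefore largely fixed beforehand, and the 3 totals are not comparable between groups. The normalized sum of the 20 features measured in all 3 tables was 42.5 to 58.7 in the uninjured libraries and 2869 (HDAC5AA replicate 1) to 18928 (HDAC5DAD replicate 3) in the injured ones. Blood left in the retinas was argued against, since the highest median of the blood list was 0.355 (SD of its genes 0.162) where a rise of at least 1 was needed. Antibody-secreting cells remained open as a source: of the measured genes that such cells use 2 of 5 passed in GFP, 3 of 6 in HDAC5AA and 5 of 6 in HDAC5DAD against Uninjured, with Jchain at 478 against 137, 458 against 125 and 749 against 135 and Xbp1 at 1881 against 1823, 1914 against 1672 and 2176 against 1805 normalized reads. A share of at least 50% was asked of HDAC5DAD and then, once the counts were known, of each group, and GFP fell short. These shares are not over the same genes, since Mzb1 had no value in GFP. Mzb1 passed in HDAC5AA and HDAC5DAD (limma adjusted p = 0.00589 and 0.000194), and without it HDAC5AA fell short of 50% too. The shares therefore show no difference between the injured groups. Jchain and Cd79b also stand in the lymphocyte list, and uninjured retina held Jchain, Xbp1 and Derl3 too. Crush, injection and virus cannot be parted by this design.

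The interferon and MHC class I lists had median log2 fold changes of 0.41 and 0.58 in HDAC5DAD against GFP, but no group difference was shown: both camera calls were lost with an estimated correlation (adjusted p = 0.373), the exact permutation p values of 0.0857 and 0.0286 were both 0.427 adjusted over the 32 lists, and no gene passed in the limma fit of the 15 libraries (10 higher and 1 lower with only the 2 groups in the fit, 8 and 5 among the libraries with at least 1% ribosomal RNA reads, 57 calls in DESeq2 and 1 in edgeR). By the bound set for it, residual ribosomal RNA reads as the whole source of these medians were argued against. With that class as a covariate they stayed at 0.360 and 0.537, and among the libraries with at least 1% of such reads at 0.278 and 0.602. The lists passing fell from 15 to 9 with the covariate. No GFP library lay under 1%, so the covariate rests on the other groups. Only HDAC5DAD replicates 1 and 4 lay at or over 1%. The medians carry no error between libraries, so these reads were not excluded as a source. Single libraries with a strong response were argued against too: the score differences of 0.48 and 0.576 were at the least 0.359, without HDAC5DAD replicate 2, and 0.458, without GFP replicate 2. More immune cells in the HDAC5DAD retinas could not be excluded or shown, since the exact two-sided permutation p of the scores was 0.114 for microglia and 0.2 for myeloid cells, with both scores higher in HDAC5DAD, also than in HDAC5AA (exact p = 0.314 and 0.286). A response to the HDAC5DAD form itself or to its virus preparation stays untested.

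Of the 57 genes deposited as lower in HDAC5AA alone, 51 lay below 0 in GFP and 57 in HDAC5DAD against Uninjured, and 0 passed in either. Their medians in GFP and HDAC5DAD were 61.2% and 67.2% of that in HDAC5AA. A threshold crossed in 1 table only would give this, but the bound written beforehand (25%) was too low to decide, since the uninjured libraries shared by the 3 tables alone would give about 50% of the HDAC5AA value. Pigmented tissue left on fewer HDAC5AA retinas was left open as well: without the 3 pigment genes the median in HDAC5AA against GFP was -0.122 (SD 0.261 over 54 genes), within its error of the bound of -0.1, on genes chosen for being low in HDAC5AA. By the bounds written beforehand the threshold would have been upheld and pigmented tissue argued against. The bound of 75% used in place of 25%, and the margin of error for pigmented tissue, were set after these values were seen, and no biological explanation was tested.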

How the results depend on the processing

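The edgeR fits, the ribosomal RNA class fits and the mean of at least 10 were chosen after seeing the data. Of the values of named genes under all alternatives, 1868 kept their side of the threshold, 86 lost the call and 12 gained one. No value with a call in the main fit or the alternative turned direction. Values without a call in either were counted as kept whatever their direction. Of the counts of genes, 181 lay within 1.5 times the reported ones and 53 did not, and of the counts of lists 22 and 8. A count of 0 beside a reported 0 was taken as within. Most alternatives of HDAC5AA against GFP and of HDAC5DAD against GFP were of this kind, which raises the 181. By construction, a log2 fold change of at least 1 as well left 453 higher and 91 lower in GFP against Uninjured (1112 and 1164 without it), 469 and 77 in HDAC5AA (1060 and 625), 651 and 86 in HDAC5DAD (1556 and 1091), and 0 and 0 between HDAC5AA and HDAC5DAD (1 and 1). With only the libraries with at least 1% ribosomal RNA reads, so with fewer samples, 772 were lower in GFP against Uninjured, 500 higher and 363 lower in HDAC5AA, 1000 higher in HDAC5DAD, 1 lower in HDAC5AA against GFP, 8 higher and 5 lower in HDAC5DAD against GFP, and 4 and 6 between HDAC5AA and HDAC5DAD. For HDAC5DAD against GFP (0 and 0 in limma), DESeq2 gave 44 and 13, only the 2 groups in the fit 10 and 1, and edgeR 1 higher; the cause was not tested. For HDAC5AA against HDAC5DAD, higher and lower, TMM scaling gave 0 and 0, pseudocount 0.1 0 and 0, edgeR 0 and 0, a mean of at least 10 0 and 0, DESeq2 2 and 4, the 2 groups alone 0 and 2, and the class as a covariate 2 lower; the cause was not tested.

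The lists passing fell with an estimated correlation to 12 of 20 in HDAC5AA and 10 of 23 in HDAC5DAD against Uninjured (GFP, 14 of 18), and to 0 of 6, 0 of 15 and 0 of 14 in HDAC5AA against GFP, HDAC5DAD against GFP and HDAC5AA against HDAC5DAD. In HDAC5DAD against GFP 9 passed with only the libraries with at least 1% ribosomal RNA reads and 9 with the class as a covariate; the cause was not tested. The calls shared with the uninjured libraries split into 2 and 2, and so with fewer samples per fit, were 535 higher and 304 lower for GFP and HDAC5AA, 617 and 396 for GFP and HDAC5DAD, and 623 and 279 for HDAC5AA and HDAC5DAD. A split of GFP into 2 and 2 was not run, since it has 3 libraries.

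Leaving out each library gave, higher and lower, 802 to 1119 and 792 to 1155 genes for GFP against Uninjured, 894 to 1040 and 446 to 607 for HDAC5AA, 1238 to 1608 and 750 to 1127 for HDAC5DAD, 0 to 2 and 0 to 0 for HDAC5DAD against GFP (2 without HDAC5DAD replicate 1), 0 to 0 and 0 to 0 for HDAC5AA against GFP, and 0 to 1 and 0 to 5 for HDAC5AA against HDAC5DAD (4 without HDAC5AA replicate 1, 5 without HDAC5AA replicate 2). Replicate numbers did not pair the libraries: 2 of 21 same-numbered pairs had a correlation over 0.1 (mean 0.00278), and 4 libraries correlated best with their own number. With the number as a block, 749 genes were lower in GFP against Uninjured, 0 higher and 0 lower between HDAC5AA and HDAC5DAD, and 10 lists passed in HDAC5AA against GFP; the cause was not tested. Depth (10939457 to 30970658 reads) limits genes with few reads, such as Ppp1r1c.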

Other observations

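The counts of other splits of the libraries were planned before the results were seen; the 2 groups of genes below were described after their values were seen, on lists fixed before.

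Mitochondrially encoded genes varied widely between libraries of the same group. All 9 measured were lower in HDAC5DAD than in GFP, with a median log2 fold change of -0.35, and all 9 higher in HDAC5AA than in HDAC5DAD, with a median of 0.35, but the genes move together and 0 passed in limma. The score of the list ranged from -0.438 to 0.192 in HDAC5DAD, -0.447 to 0.885 in HDAC5AA and 0.0127 to 0.260 in GFP. The exact two-sided permutation p was 0.143 for HDAC5DAD against GFP and 0.4 for HDAC5AA against HDAC5DAD, and the latter difference, 0.318, was 0.0741 without HDAC5AA replicate 4. The list holds mt-Rnr1, one of the ribosomal RNA features, so its score overlaps that technical measure. HDAC5AA replicate 4 had the highest share of those features (9.87%) and the fewest reads. No difference between the groups is read from this list.

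Genes of amacrine cells, the inner retinal neurons in which Prdm13 acts, had a median log2 fold change of 0.09 in HDAC5AA against HDAC5DAD, 18 of 25 above 0 (limma camera adjusted p = 8.53e-06, and adjusted p = 0.415 with an estimated correlation). By the scores per library the exact two-sided permutation p was 0.0857 (0.610 adjusted over the 32 lists), so no difference was shown. None passed over all genes and 4 were higher adjusted over the list alone, among them the glycine transporter gene Slc6a9 at 2717 ± 157 (SD, n = 4) against 2294 ± 154 (n = 4) and the acetylcholine transporter gene Slc18a3 at 253 ± 14.9 against 198 ± 12.8. The sum of crystallin reads, genes of the lens, was 1893 in GFP replicate 2 and 41.7 to 481 in the other 14 libraries.

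Among the 35 splits of the libraries of each comparison into groups of the same sizes, the real split gave the most genes in each comparison with Uninjured. A share of 1 of 35 is the smallest that these splits allow, and it bears on these libraries only. The other splits mix injured and uninjured libraries, which widens the spread within groups, so their low counts are not those of unchanged groups. For GFP 1 of 35 splits gave as many genes as the real one (2276 genes; highest other 16), for HDAC5AA 1 of 35 (1685; highest other 5, in the split that follows the class of ribosomal RNA reads) and for HDAC5DAD 1 of 35 (2647; highest other 13). For HDAC5AA against HDAC5DAD chance was not excluded: 5 of 35 splits gave as many as the real 2 genes, Prdm13 and Agtpbp1, and the highest other gave 31. For HDAC5AA against GFP and for HDAC5DAD against GFP the real split gave 0 genes in limma, so that 35 of 35 and 35 of 35 splits gave as many by construction, and these counts decide nothing about chance.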
